A study of Mus musculus with 22 samples.

How the data were processed

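RNA sequencing was run on microglia sorted from mouse retina, at postnatal day 17 (P17) and postnatal day 31 (P31), from animals labelled as Vldlr knockout (KO) or control. Vldlr encodes the very low density lipoprotein receptor. The labels give 7 control and 5 KO libraries at P17, and 5 control and 5 KO libraries at P31. Nothing in the labels says that each library came from a separate animal, so p-values measure the spread between these libraries.

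The submitters' processing notes name FastQC 0.72, STAR 2.7.5b, featureCounts, R 3.5.3, DESeq2 1.22.2 and the mm10 build, without roles. The annotation version and the strand setting of the counting are not given in the sources used here. The deposited table holds 28984 genes and 22 library columns. The values are a normalised signal: gene read counts that the authors divided by a size factor per library, as the values themselves show, because every library's values are whole multiples of what 1 read is worth. Dividing by that step gave whole reads for 100% of 349420 non-zero values, within a relative tolerance of 1e-06. The deposited table also gives the authors' own log2 fold changes and adjusted p-values for 4 comparisons.

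The recovered reads summed to 23.9 to 54.0 M per library, and 1 read was worth 0.578 to 1.29 normalised counts. Size factors implied by the table were compared with those DESeq2 computes on the same reads. In P17 KO library 1 the deposited factor was 0.814 relative to the geometric mean, while DESeq2 gave 0.353 and TMM 0.368. The deposited scaling was kept for the main results, and it set this library's values low.

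The design fixed before the data were examined assumed raw counts and edgeR. Because the table holds normalised values, the main test was instead limma 3.58.1 in R 4.3.3 with a mean-variance trend and robust moderation, on log2(normalised count + 10). Genes needed a value of at least 30 in at least 5 libraries, which left 12868. All 22 libraries entered a fit with 4 group means, and 5 contrasts were taken from it. P-values were adjusted by Benjamini-Hochberg, with calls at an adjusted p under 0.05. Fold changes are on the log2(value + 10) scale, which understates changes of low genes. For a gene at 0 in every library of a group, the fold is a lower bound against the value of 3 reads per library, which covers counting error only.

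Gene lists were fixed before the data were examined, 33 in all, and tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry. List scores, the mean log2(normalised count + 10) over members in place of the planned CPM, were compared between genotypes by two-sided exact permutation tests, adjusted over the 33 lists. Named genes followed a rule fixed at the same time. It took Vldlr and, per contrast, up to 8 higher and 8 lower called genes with the largest fold change. Those had a mean of at least 5 CPM, calculated from the recovered reads, in the higher group and no overlap between libraries. Symbols beginning with Gm and a digit, ending in Rik or containing -ps were left out, and the difference between KO effects had no overlap condition. Up to 4 members with the smallest p were added from each list described. Gene positions are from GENCODE vM21 on mm10, to which 99.8% of genes matched by Ensembl identifier.

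The pipeline was tested on simulated reads for the 12868 genes with 200 changed genes. For KO against control at P17 it recovered 17.3% of 2-fold, 56.1% of 4-fold and 64.5% of 8-fold changes. At P31 it recovered 12.1%, 52.2% and 53.7%. For age it recovered 6.6%, 47.7% and 64.9% in controls and 16.9%, 45.3% and 66.2% in the KO. For the difference between the KO effects it recovered 1.5%, 22.2% and 44.9%. Unchanged genes made up 7.5% of calls at P17 and 4.8% at P31, 7.8% and 5.4% for age in controls and KO, and 8% for the difference, against a threshold of 5%. The simulation drew each gene independently and scaled libraries by TMM, not by the deposited size factors. It leaves out variation shared between genes and the deposited factor of P17 KO library 1, so shares in the real data may differ.

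Alternatives were edgeR 4.0.16, DESeq2 1.42.0 and limma voom on recovered reads, other scalings, filters and pseudocounts, covariates (a rod photoreceptor score, a Y-linked score, and a surrogate variable from sva 3.50.0), a replicate block, only the groups compared, and each library left out in turn. Added after seeing the data were TMM and upper-quartile scaling within limma, pseudocounts of 1 and 64, edgeR with TMM, the Y-linked score, and P31 libraries with Xist and without Y-linked reads. No pair of libraries within a group agreed within sampling noise, so none was counted as a repeat.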

Results

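Transcript levels were measured in sorted retinal microglia, the resident macrophages of the retina, from Vldlr KO and control mice at P17 and P31. The series title names the question as the part microglia play in retinal angiomatous proliferation, a growth of abnormal vessels, in this knockout. Libraries held 25.5 to 32.3 M (M, mega) reads in the P17 controls, 23.9 to 33.7 M in the P17 KO, 30.8 to 54.0 M in the P31 controls and 29.0 to 39.6 M in the P31 KO.

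Vldlr (ENSMUSG00000024924, mm10 chromosome 19, 27216484 to 27254231) was lower in the KO at P17. Its normalised count was 351 ± 284 (SD, n = 7) in controls and 6.71 ± 9.19 (SD, n = 5) in the KO, a log2 fold change of -4.03 ± 0.96 (SE, limma adjusted p = 0.0282). The P17 controls held 49 to 790 Vldlr reads each, and the P17 KO libraries held 0, 17, 0, 13 and 0. At P31, control 1 held 875 reads and the other controls held 0, while the KO libraries held 0, 1, 65, 1 and 14. The P31 log2 fold change was -0.46 (limma adjusted p = 0.898), so Vldlr did not check the genotype labels at P31. The P17 call was lost in 17 of 38 alternatives, among them leaving out P17 control 1, 3, 4 or 7 or P17 KO library 1, 3 or 5, where the adjusted p lay between 0.0581 and 0.0948. With the rod score as a covariate the P17 log2 fold change of Vldlr was -2.225 (limma adjusted p = 0.317), and with the Y-linked score -2.53 (limma adjusted p = 0.224). Rod scores were 12.9, 13.1 and 13.1 in P17 controls 1, 3 and 4, which held 474, 369 and 790 Vldlr reads. P17 controls 2, 5, 6 and 7, with rod scores of 10.956, 9.088, 11.398 and 10.553, held 89, 49, 53 and 380. Vldlr reads thus did not follow the order of the rod scores across the P17 controls. P17 KO libraries 2 and 4, at 11.025 and 10.92, held 17 and 13, fewer than any P17 control. The rod score was 11.2 in P31 control 1, against 6.43 to 7.89 in the other P31 controls. Which part of the gene the knockout removes is not given in the sources used here.

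**Figure D1:**
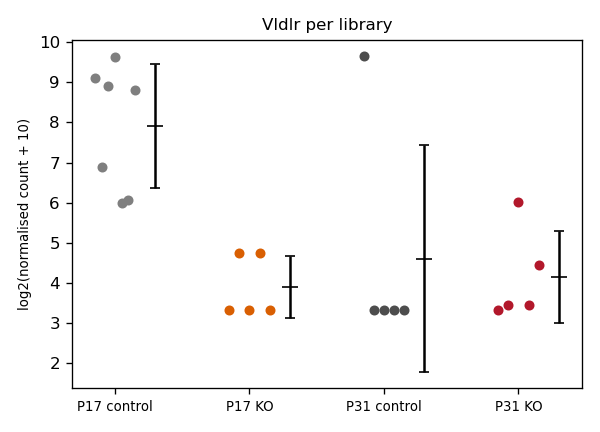
Vldlr per library as log2(normalised count + 10), with 1 point per library and the group mean ± SD beside it. P17 controls lie above the P17 KO libraries, while 4 of 5 P31 controls are at 0.

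Rod photoreceptor and sex markers varied between the libraries. Rod list scores averaged 11.58 in controls and 9.48 in the KO at P17, and 7.84 and 9.72 at P31 (exact permutation adjusted p = 0.153 and 0.244). Rhodopsin, the rod visual pigment, ranged from 5827 to 121797 normalised counts in P17 controls, from 1875 to 18370 in the P17 KO, from 1208 to 22842 in P31 controls and from 4590 to 40190 in the P31 KO. At a level of 100 normalised counts, Y-linked reads without Xist were found in 5 P17 controls and 2 P31 controls, and in 0 KO libraries. Xist without Y-linked reads was found in 0 P17 controls, 3 P17 KO, 3 P31 control and 5 P31 KO libraries. The remaining 2 P17 controls (4 and 6) and 2 P17 KO libraries (1 and 4) held both. In P17 control 6 Xist was at 4496.1 and the Y-linked genes at 2188.5, and in P17 KO library 1 at 2861.7 and 795. Whether these libraries held RNA of more than 1 animal is not given in the labels.

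At P17, genes higher in the KO included Ccr6, a chemokine receptor, and Slc1a3, a glutamate transporter that is also on the list of glial markers. That list did not rise as a set, with a median log2 fold change of -1.20 and 4 of 15 tested members above 0. Ccr6 rose from 25.4 ± 27.5 (SD, n = 7) to 2832 ± 1573 (SD, n = 5) normalised counts, a log2 fold change of 6.63 ± 0.62 (SE, limma adjusted p = 2.52e-07). Slc1a3 rose from 2147 ± 722 to 57290 ± 29320, and Angptl7 from 100.2 ± 76.9 to 3059 ± 1589. Hebp1 rose 17.1-fold. Clec7a, the beta-glucan receptor dectin-1, fell from 4417 ± 1124 to 262 ± 196, and Slc2a5, a fructose transporter, from 17880 ± 1873 to 3036 ± 4353. Mrc2, a collagen receptor, fell from 923 ± 482 to 22.1 ± 43.9, and the non-coding AI506816 from 1633 ± 468 to 9.78 ± 12.5. Ranbp3l and BC018473 were at 0 in every P17 control and averaged 199 and 194 in the KO, at least 51.9-fold and 50.5-fold higher. The pseudogene Rps3a3 rose 50.0-fold, a value that depends on how reads shared with similar ribosomal protein genes were counted. Lower genes also included Ifi209 (log2 fold change -3.87) and Mocs1 (-3.39), with Gucy2e, a photoreceptor guanylate cyclase, at -3.86 and Fam189a2 higher at 3.95. Leaving out 1 library ended these calls, with the highest adjusted p in brackets. Gucy2e was lost without P17 control 1, 2, 3, 4, 5 or 6 or P17 KO 1, 2, 3 or 5 (up to 0.137). Fam189a2 was lost without P17 control 2 or P17 KO 3 (up to 0.0835).

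Of 35 tested type I interferon response genes, 3 fell at P17, 0 rose and 32 did not pass, while 15 were lower when adjusted over the list alone. Ifit3b fell from 132 ± 34.1 to 22.9 ± 26.5 (limma adjusted p = 0.00331). Oas1a fell by 1.98 and Ifi204 by 2.68 on the log2 scale. Rsad2 was at 315.5 and 31.3 (limma adjusted p = 0.0751). The list was called by camera (adjusted p = 4.83e-08) but not with an estimated correlation (adjusted p = 0.138, and 0.0281 without P17 KO library 1). The number of called interferon genes at P17 was 6 without P17 KO 1, 5 without P31 KO 4, and 1 without P17 control 1, 2, 4 or 7, P17 KO 4 or P31 control 3 or 4. The median log2 fold change of the list was -1.02, and -1.33 without P17 KO library 1. Its score was 8.14 in controls and 6.87 in the KO (exact permutation adjusted p = 0.0416). Rod markers, with a median log2 fold change of -2.04 at P17, had 0 of 20 members called over all genes. These calls ended when 1 library was left out, with the highest adjusted p in brackets. Oas1a was lost without P17 control 1, 2, 3, 4 or 7, P17 KO 2, 4 or 5, P31 control 3 or 4 or P31 KO 1 (up to 0.109). Ifi204 was lost in 13 of 22 fits, all but those without P17 control 3, P17 KO 2 or 5, P31 control 5 or P31 KO 1, 2, 3, 4 or 5 (up to 0.137).

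In limma, 195 of 12868 genes passed at P17, 99 higher and 96 lower in the KO. The median log2 fold change of all tested genes was -0.30, -0.07 with TMM scaling and -0.03 without P17 KO library 1. The share of higher genes was 50.8% with the deposited scaling, 59.5% with TMM scaling in limma and 86.3% in edgeR with TMM, which changes the test as well and called 190 genes. The count was 115 with a rod score as a covariate, 112 with a Y-linked score and 747 in DESeq2.

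At P31, DNA replication and cell division genes rose in the KO. Of 40 tested cell cycle genes, 20 rose, 0 fell and 20 did not pass, and 34 were higher when adjusted over the list alone. The median log2 fold change was 2.58, also with Ccne1 at its lower bound (camera adjusted p = 5.55e-35, and adjusted p = 0.000189 with an estimated correlation). Ccnb2, a mitotic cyclin, rose from 72.0 ± 150.4 to 899 ± 354 (SD, n = 5 each), and Cenpa, a centromeric histone, from 45.9 ± 65.5 to 857 ± 612. Mcm6, part of the replicative helicase, rose from 704 ± 160.5 to 3836 ± 1273, a log2 fold change of 2.38 ± 0.39 (SE, limma adjusted p = 0.000496). Ccne1, a G1/S cyclin, was at 0 in every P31 control and averaged 365 in the KO, at least 128-fold higher. Dtl, which acts in replication-coupled protein turnover, rose 70.5-fold. Mki67 (log2 fold change 3.28, limma adjusted p = 0.12), looked up after the values were seen, did not pass.

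Disease-associated microglia genes went both ways at P31. Of 29 tested, 6 rose, 2 fell and 21 did not pass. Spp1, which encodes osteopontin, rose from 533 ± 718 to 9676 ± 8415, Fabp5, a fatty acid binding protein, from 170 ± 172 to 2185 ± 941, and Igf1 from 259 ± 380.5 to 1057 ± 402. Gpnmb, Lgals3 and Apoe were also higher. Clec7a fell from 7361 ± 906 to 1022 ± 326, and Timp2 by 0.58 on the log2 scale. The list was called by camera (adjusted p = 0.00304) and not with an estimated correlation (adjusted p = 0.0504). Of 35 interferon response genes, 5 fell, 0 rose and 30 did not pass at P31, among them Ifi204 (log2 fold change -5.00), Rsad2 (-4.84), Sp100 (-1.75), Ifi213 (-2.92) and Slfn2 (-1.47). The interferon list was called by camera (adjusted p = 1.12e-12) and with an estimated correlation (adjusted p = 0.0229). Of 26 antigen presentation genes, 3 fell and 1 rose. H2-T23 fell from 9665 ± 1036 to 2807 ± 400, H2-D1 1.78-fold and H2-DMa 2.07-fold, while H2-Eb1 rose 13.2-fold (camera adjusted p = 0.00236, and adjusted p = 0.239 with an estimated correlation). The number of called interferon genes at P31 was 11 without P17 KO 1, and 3 without P31 control 1, 3 or 4 or P31 KO 2 or 5. Called antigen presentation genes were 3 higher and 7 lower without P17 KO 1, 0 higher and 2 lower without P31 control 2 or P31 KO 3, and 0 higher and 1 lower without P31 control 3 or 4 or P31 KO 4. The rod list had a median log2 fold change of 1.87 at P31, with 0 of 20 members called. Leaving out 1 library ended these calls, with the highest adjusted p in brackets. Ifi213 was lost without P31 control 1, 3, 4 or 5 or P31 KO 2, 3 or 5 (up to 0.103). Slfn2 was lost at least without P31 control 1, 3 or 4 or P31 KO 2 or 5. H2-DMa was lost in 13 of 22 fits, all but those without P17 control 1, 2, 4 or 6 or P17 KO 1, 2, 3, 4 or 5 (up to 0.101). H2-Eb1 was lost without P31 control 2, 3 or 4 or P31 KO 3 or 4 (up to 0.0686). H2-D1 was lost without P31 control 3 or 4 or P31 KO 1, 4 or 5 (up to 0.0787).

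**Figure D2:**
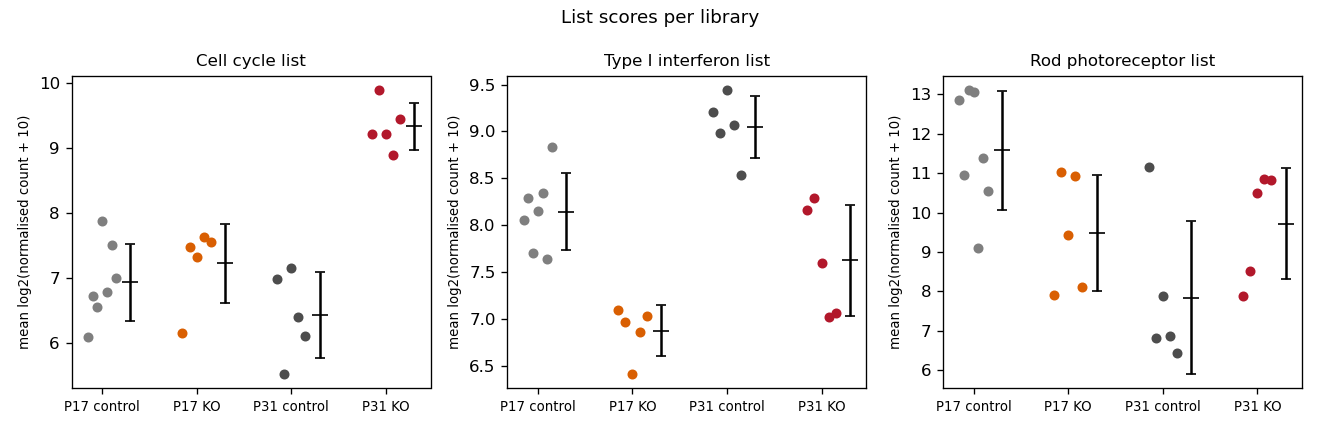
Mean log2(normalised count + 10) of the cell cycle, type I interferon and rod lists, with 1 point per library and the group mean ± SD beside it. The cell cycle score averaged 6.43 in P31 controls and 9.33 in the P31 KO.

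Other P31 differences were in Ets1, a transcription factor, which fell from 6009 ± 1776 to 69.8 ± 108, and Pear1, from 1390 ± 639 to 69.8 ± 124. Lrba fell 34.3-fold and Zfp984 37.6-fold. Cxcl13, a B cell chemoattractant, and Ifi202b, of the interferon-inducible p200 family, were at 0 in every P31 control and averaged 618 and 437 in the KO, at least 217-fold and 154-fold higher. Ccr6, Angptl7 and Rps3a3 were again higher, and Mrc2, Slc2a5 and AI506816 lower.

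In limma, 371 genes passed at P31, 218 higher and 153 lower. The count was 864 without P17 KO library 1, which shares in the estimate of the spread, 212 in edgeR with TMM and 928 in DESeq2.

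The KO differences called at both ages overlapped. Of 99 genes higher at P17 and 218 at P31, 82 were shared, against 1.68 for independent lists (Fisher's exact test p = 8.1e-135). Of 96 and 153 lower genes, 40 were shared, against 1.14 (Fisher's exact test p = 4.19e-53), and 1 gene, Rims2, was called in opposite directions. The ages share no libraries, but both contrasts use the same estimate of spread per gene. The expected numbers for independent lists may thus be too low, and the p-values of Fisher's exact test too small. Processed pseudogenes made up 31.3% of the genes higher at P17 and 15.6% of those higher at P31, but 1.4% of genes tested (Fisher's exact test adjusted p = 2.14e-33 and 6.88e-26). Counts of such copies depend on how reads matching the parent gene were assigned.

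**Figure D3:**
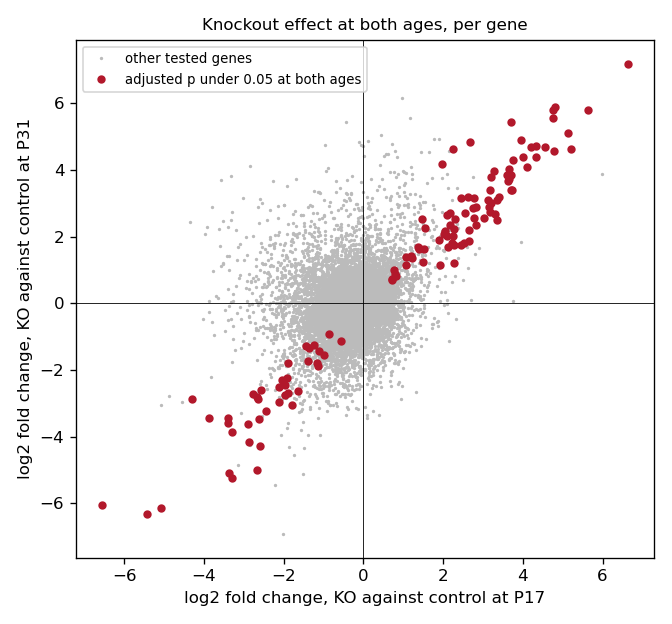
Log2 fold change of KO against control at P17 (x axis) and at P31 (y axis) for 12868 genes. The 122 genes called in the same direction at both ages are marked.

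The KO effect differed between the ages for 6 genes. Rims2, a presynaptic gene, averaged 144.5 ± 127 (SD, n = 7) in P17 controls and 4.25 ± 5.90 in the P17 KO, and 2.93 ± 6.56 in P31 controls and 249.5 ± 155 in the P31 KO (SD, n = 5 each), a difference of 6.95 ± 1.04 on the log2 scale (SE, limma adjusted p = 0.00544). Mcm6 (difference 3.63), Dtl (5.17) and Brca1 (4.73), a DNA repair gene, were also higher, and Ets1 (-4.91) and BC018473 (-3.70) lower. The cell cycle list had a median difference of 2.53 (camera adjusted p = 1.96e-21, and adjusted p = 0.00342 with an estimated correlation). Of its 40 members, 1 rose (2 without P31 control 3), 0 fell and 39 did not pass. Rod markers moved further, with a median difference of 3.83, 18 of 20 higher when adjusted over the list alone and 0 called over all genes (camera adjusted p = 1.91e-16, and adjusted p = 0.246 with an estimated correlation). With the rod score as a covariate the Rims2 difference was 5.17 (limma adjusted p = 0.424). The cell cycle list was still called with that covariate by camera at the preset correlation (adjusted p = 1.39e-22). Ccnb2, Cenpa and Bub1b had differences of 4.60, 4.05 and 5.70 with limma adjusted p = 0.135, 0.235 and 0.309. In limma 6 genes passed and 1027 had an unadjusted p under 0.05. With the rod score as a covariate 0 passed and 355 had an unadjusted p under 0.05. That is fewer than a share of 0.05 of the 12868 tested genes, which chance alone would give. Without a covariate edgeR with TMM called 3 and DESeq2 358. The count was 3 without P17 control 2, 3 or 7, P17 KO library 5, P31 control 2 or 4, or P31 KO library 1 or 3, and 7 without P17 KO library 1, of which 3 were shared. These calls ended when 1 library was left out, with the highest adjusted p in brackets. Dtl was lost in 19 of 22 fits, all but those without P17 control 1, P17 KO 2 or P31 control 3 (up to 0.0979). Brca1 was lost in 13 of 22 fits, all but those without P17 control 1, 4, 5 or 6, P17 KO 2, P31 control 1 or P31 KO 2, 4 or 5 (up to 0.0807). BC018473 was lost in 19 of 22 fits, all but those without P17 KO 2, 3 or 4 (up to 0.0851).

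Between P17 and P31 in controls, Apoe, a lipid carrier, fell from 362600 ± 134200 (SD, n = 7) to 39120 ± 23220 (SD, n = 5), a log2 fold change of -3.30 ± 0.32 (SE, limma adjusted p = 6.61e-06). Of 12 tested lipid efflux genes, 3 fell, with Abcg1, a sterol transporter, 3.23-fold and Apoc1 6.29-fold lower. Abca1 was at 7569 and 2936 (limma adjusted p = 0.137). That list was called by camera (adjusted p = 0.00508) and not with an estimated correlation (adjusted p = 0.318). Of 18 glycolysis genes, 5 fell and 0 rose, namely Aldoa (log2 fold change -0.89), Ldhb (-0.92), Eno1 (-1.15), Gapdh (-0.76) and Ldha (-0.90), with camera adjusted p = 1.78e-11 and adjusted p = 0.0351 with an estimated correlation. Interferon response genes had a median log2 fold change of 1.08, with 1 of 35, Phf11b, called (camera adjusted p = 1.86e-13, and adjusted p = 0.0351 with an estimated correlation). Ifit3b, Sp100 and Ifi27l2a were at 1.79, 1.21 and 1.55 with limma adjusted p = 0.0554, 0.0592 and 0.0841. Markers of Mueller glia and astrocytes had a median of -1.59 in the same comparison, and rod markers -3.67. Of 15 glial markers, 0 were called over all genes and 8 were lower when adjusted over the list alone. That glial list was called by camera (adjusted p = 7.86e-05) and not with an estimated correlation (adjusted p = 0.113). With the rod score as a covariate, camera at the preset correlation still called glycolysis (adjusted p = 0.000204) and lipid efflux (adjusted p = 0.00133). Over all genes, no glycolysis gene passed with that covariate, while Apoe did. Called glycolysis genes numbered 12 without P17 KO 1, 3 without P31 control 2, and 2 without P17 control 3 or 4 or P31 control 4 or 5. Called lipid efflux genes numbered 6 without P17 KO 1. The number of called interferon genes with age in controls was 10 without P17 KO 1, and 2 without P17 KO 2, 3 or 5, P31 control 2 or P31 KO 4 or 5. It was 0 without P17 control 4 or P31 control 4. Leaving out 1 library ended these calls, with the highest adjusted p in brackets. Apoc1 was lost without P17 control 4 or P31 control 3 or 4 (up to 0.0537). Eno1 was lost without P17 control 3 or 4 or P31 control 4 or 5 (up to 0.0682). Gapdh was lost without P17 control 3 or 4 or P31 control 2, 4 or 5 (up to 0.075). Ldha was lost in at least the same fits as Gapdh. Phf11b was lost without P17 control 4 or P31 control 4 (up to 0.0705).

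Photoreceptor genes fell with age in controls. Of 20 rod markers, 10 fell and 0 rose, among them Sag (-4.34 on the log2 scale), Cngb1 (-4.62), Nr2e3 (-5.72) and Pde6g (-3.17), with camera adjusted p = 2.96e-21 and adjusted p = 0.11 with an estimated correlation. Called rod markers numbered 17 without P31 control 1, 16 without P17 control 5 or P17 KO 1, 6 without P17 control 6 or P31 KO 2, 5 without P17 control 2, 4 without P31 control 2, and 3 without P17 control 1, 3 or 4 or P31 control 3, 4 or 5. Genes with the largest falls included Drd4 (-5.37), Lrit1 (-5.37), Ndrg1 (-5.11), Otx2 (-5.02), Krt18 (-4.54) and Cacna2d4 (-4.28). Pcbp3 and Col9a1 averaged 438 and 248 in P17 controls and were at 0 in every P31 control, at least 154-fold and 87.2-fold lower. Wee1, a kinase that restrains mitosis, rose 8.68-fold, Lox, a collagen cross-linking enzyme, 8.35-fold, Nav2 3.82-fold and Ccnd1, a G1 cyclin, 2.82-fold. Wdfy1, Scaper, Kcnip3 and Mir99ahg rose between 2.50-fold and 3.73-fold. In limma 188 genes passed, 48 higher and 140 lower at P31. The share of higher genes was 25.5%, and 48.1% of 52 genes in edgeR with TMM. With the rod score as a covariate 3 passed, Apoe, Nav2 and the predicted gene Gm10800, the last named after its values were seen. The count was 877 without P17 KO library 1, 93, 61 and 54 without P17 control 1, 3 or 4, and 108, 115, 62 and 67 without P31 control 2, 3, 4 or 5. These calls ended when 1 library was left out, with the highest adjusted p in brackets. Pde6g was lost without P17 control 1, 3 or 4 or P31 control 2, 3, 4 or 5 (up to 0.0869). Lrit1 was lost without P17 control 1, 3 or 4 or P31 control 2, 3 or 4 (up to 0.0763). Cacna2d4 was lost without P17 control 3 or 4 or P31 control 4 or 5 (up to 0.0599). Lox was lost without P17 control 3 or P31 control 2, 4 or 5 (up to 0.0743). Wdfy1 was lost without P17 control 4 or P31 control 4 or 5 (up to 0.0705). Scaper was lost without P17 control 3 or 4 or P31 control 2, 4 or 5 (up to 0.0847). Kcnip3 was lost without P17 control 4 or P31 control 2, 3 or 4 (up to 0.0697). Mir99ahg was lost without P31 control 5 (up to 0.0543).

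In the KO, Apoe also fell with age, from 926200 ± 301300 to 109700 ± 29140 (SD, n = 5 each; limma adjusted p = 3.57e-05). Gpnmb, a lysosomal glycoprotein, rose from 58.2 ± 74.1 to 3176 ± 2386, and Lgals3, which encodes galectin-3, from 89.6 ± 58.6 to 1170 ± 434. Cxcl13, Enpp4, Dtl, Rims2, Brca1 and Fignl1 rose between 13.6-fold and 26.1-fold. Ets1 fell 32.7-fold, Lag3, an immune checkpoint receptor, 5.56-fold, Ppif 9.25-fold and Lrrc8a 3.18-fold. Ifitm10 and Mospd3 fell 4.27-fold and 3.40-fold, and BC018473 averaged 194 at P17 and 0.542 at P31. Of 40 cell cycle genes, 3 rose, with Mcm6 5.98-fold, Ccne2 13.3-fold and Mcm2 5.72-fold higher, 0 fell and 37 did not pass. Tk1 was at 125 and 547 (limma adjusted p = 0.0576). The number of called cell cycle genes with age in the KO was 9 without P17 KO 1, and 5 without P31 control 2. The cell cycle list was called by camera (adjusted p = 1.99e-19) and with an estimated correlation (adjusted p = 0.00575). In limma 114 genes passed, 65 higher and 49 lower at P31, against 535 without P17 KO library 1, 72 without P17 KO library 3, 74 without P31 KO library 4 and 8 with only the 2 groups compared. The share of higher genes was 57.0%, 27.1% without P17 KO library 1 and 28.3% of 159 genes in edgeR with TMM. Leaving out 1 library ended these calls, with the highest adjusted p in brackets. Gpnmb was lost without P17 KO 4 or P31 KO 3 (up to 0.0506). Fignl1 was lost without P17 KO 3 or 5 or P31 KO 1, 2, 3, 4 or 5 (up to 0.078). Ppif was lost in 17 of 22 fits, all but those without P17 KO 1, P31 control 2 or 5 or P31 KO 2 or 5 (up to 0.12). Ifitm10 was lost without P17 KO 3 or 4 or P31 KO 4 (up to 0.0729). Mospd3 was lost in 14 of 22 fits, all but those without P17 control 6, P17 KO 1 or 5, P31 control 1, 2 or 5 or P31 KO 2 or 3 (up to 0.0997). Lrrc8a was lost without P17 KO 3 (up to 0.0641).

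In the authors' deposited table, 451 genes had an adjusted p under 0.05 at P17 and 797 at P31 for KO against control, and 779 and 718 for age in control and KO. Of these, in the same order, 62, 120, 84 and 97 had an absolute log2 fold change over 15.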

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

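The tests of size factor in P17 KO library 1, of strain variants and pseudogene reads in the shared genes, and of sex, photoreceptor RNA and other cell types in the cell cycle list were chosen only after the result was seen. Of 48 sets of 5 or 7 libraries examined for a library far from its group, 9 held one, where chance gives about 1 in 20.

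Only 4 read measures, Vldlr and the lists described in the report were examined in this way, and P17 KO library 1 stood apart from its group in 6 of these. Mitochondrial genes took 1.127% of its reads (0.256% to 0.413% in the other libraries of its group), ribosomal protein genes 2.561% (0.503% to 0.752%) and its 10 most abundant genes 34.46% (15.07% to 18.14%). Its list scores were 11.18 for disease-associated microglia (11.93 to 12.18), 6.159 for the cell cycle (7.323 to 7.633) and 9.801 for lipid efflux (10.92 to 11.29). Cst3, which encodes cystatin C, took 11.32% of its reads, against a median of 2.868% over all other libraries of both ages and genotypes, and Apoe 4.59% against 0.575%. Apoe differed with age and genotype, so its median over all groups overstates the distance from this library's own group. Among lists not examined in this way, looked up later, its scores were also low for homeostatic microglia (13.9, against 15.4 to 15.8) and lysosome genes (12.215, against 13.757 to 13.994).

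The authors' size factor for this library may account for its low list scores, since its median deviation was -1.116 with the deposited scaling, and with TMM scaling 0 of the 3 scores were still under the group past the bound used (12.158 against 11.882 to 12.091 for disease-associated microglia, 6.944 against 7.322 to 7.547 for the cell cycle and 10.786 against 10.918 to 11.213 for lipid efflux). It does not account for the rest, because no factor moves shares of reads or the correlation of log2 reads, which was 0.687 at most with the rest of its group, against 0.909 to 0.964 for other pairs over 8940 genes. Its 10 most abundant genes alone do not either, since without them its median deviation was -0.77 under total-count scaling, against -0.067 to 0.143 elsewhere. Its deviations fell with exonic length, with a Spearman correlation across genes of -0.387 against -0.171 to 0.322 in the other libraries, so loss of long transcripts, through RNA quality or library preparation, may contribute. Genes are not independent replicates, and no biological explanation was tested, since the labels set this library apart in nothing. This library held both Xist and Y-linked reads, as did P17 KO library 4 and P17 controls 4 and 6.

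The cell cycle list differed between the KO effects at P31 and P17, with a median of 2.53, and so did Mcm6 (3.63), Dtl (5.17), Brca1 (4.73), Rims2 (6.95), Ets1 (-4.91) and BC018473 (-3.70). For the rise of the list at P31, sex as the whole cause is argued against by a median of 2.80 in the libraries with Xist and without Y-linked reads, 3 control and 5 KO (adjusted p = 0.000866 with an estimated correlation). Photoreceptor RNA is argued against by a median of 2.51 with the rod score as a covariate (adjusted p = 0.000254 with an estimated correlation). Cells of another blood or vessel type cannot be told apart, because only 5 of 7 such marker lists had 3 tested members. The highest median among them was 0.57, for monocytes and infiltrating macrophages. Of the 9 tested members of that list, 7 had a log2 fold change above 0 and 0 were called (camera adjusted p = 0.123). The sort would remove Ly6C and Ly6G positive cells, but rod RNA was found in the sorted libraries all the same. An effect of the knockout on division stays open as untested, and Mki67 at P31 (log2 fold change 3.28, limma adjusted p = 0.12) did not pass.

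In limma 122 genes were called in the same direction at both ages, while the KO effects of all tested genes correlated at 0.303 between the ages. Sex as their cause is argued against by the P31 controls. There the difference between 3 libraries with Xist and 2 with Y-linked reads was a median of 0 of the KO effect. The bootstrap interval (-0.001 to 0.01) was drawn over genes and does not measure the spread between these few libraries. For the 31 processed pseudogenes among them, a part of the pattern, reads shared with the parent gene cannot be told apart. Of 11 pairs in all, a loss could be seen in 3. In 2 of these the parent lost at least 0.5 of the gain at P31, namely Ndufs5 (347 to 53.4) and Atp6v0c (3335 to 1405). In the other, Tdg went from 169 to 154 against a gain of 101. For a strain variant, 25.4% of the shared genes had another within 1 Mb, against a median of 17.2% in 1000 random draws, of which 54 were as high; this missed the bound set for it, which was itself wrong, because a background that differs throughout the genome need not cluster. Differences of strain between KO and control animals may thus remain beside the knockout itself as a candidate explanation. Within 10 Mb of Vldlr, 1 of 80 tested genes was shared, close to the share over all tested genes (122 of 12868).

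Vldlr was at 801.7 normalised counts in P31 control 1 and at 0 in the other P31 controls, and at 55.15 in P31 KO library 3 against 0 to 11.62 in the other P31 KO libraries. The antigen presentation score of P31 KO library 5 was 10.09, against 10.73 to 10.89 in its group.

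Other splits of the libraries into groups of the same sizes were drawn, 100 per comparison with the real one included. For KO against control, 1 split gave as many genes at P17 (195 genes, highest other 11) and 1 at P31 (371 genes, highest other 7), so chance can be excluded. For age in controls, 1 split, the real one, reached the count (188 genes, highest other 137), so chance can be excluded for that count. For age in the KO, 2 splits did (114 genes, highest other 176). Another split thus called more genes than the real one, and fitting only the 2 groups compared gave 8, so chance was not excluded there. For the difference between KO effects, 2 splits reached the count (6 genes, highest other 104). These splits exchanged genotype labels within each age, so they removed the KO effects along with any difference between them. They therefore cannot decide whether the 6 calls exceed chance. A split that calls many times the real count points to a structure of the libraries other than their groups.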

How the results depend on the processing

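TMM and upper-quartile scaling within limma, pseudocounts of 1 and 64, edgeR with TMM, the Y-linked covariate and the Xist libraries at P31 were chosen only after the data were seen. The cause of changes was not tested, except where fewer genes or libraries entered. Of the alternatives for named genes, 3731 kept the call or its absence, 594 lost a call, 42 gained one and 5 reversed. All 5 were Vldlr at P31, at 0.316 with a pseudocount of 1, 0.469 with the Y-linked covariate, 0.810 with the Xist libraries, 0.032 in voom and 0.810 without P31 control 1, with a range of -0.932 (without P31 KO 3) to 0.810 over omissions of 1 library. Fitting only the groups compared was not run for the difference, which needs all 4. KO against control at P17 gave 195 genes, but 120 with a replicate block, 115 with the rod covariate, 112 with the Y-linked covariate, 419 in voom and 747 in DESeq2, and 135 to 216 without 1 library (P17 KO 3, P17 KO 1). At P31 it gave 371, but 212, 221 and 220 in edgeR with TMM, RLE and upper-quartile factors and 928 in DESeq2, and 311 to 864 without 1 library (P31 control 4, P17 KO 1). Age in controls gave 188, but 65 without a filter, 108 with a stricter filter, 40 with the block, 3 with the rod covariate, 408 with a surrogate variable, 50 with the Y-linked covariate, 1017 with only the 2 groups compared, 107 with the Xist libraries, 586 in voom, 52, 48 and 48 in edgeR with TMM, RLE and upper-quartile factors and 850 in DESeq2, and 54 to 877 without 1 library (P17 control 4, P17 KO 1). Age in the KO gave 114, but 184 with TMM and 185 with upper-quartile scaling, 54 with the block, 405 with a surrogate variable, 8 with only the 2 groups compared, 650 in voom and 1008 in DESeq2, and 72 to 535 without 1 library (P17 KO 3, P17 KO 1). The difference between KO effects gave 6, but 3 with a stricter filter, 1 with the block, 0 with the rod covariate (355 at an unadjusted p under 0.05), 10 with the Xist libraries, 3 in voom, 3, 3 and 3 in edgeR with TMM, RLE and upper-quartile factors and 358 in DESeq2, and 3 to 7 without 1 library. The share of higher genes at P17 was 50.8%, but 60.6% with upper-quartile scaling, 64.4% in voom, 66.5% in DESeq2, and 86.3%, 85.8% and 89.7% in edgeR with TMM, RLE and upper-quartile factors. In controls with age it was 25.5%, but 51.4% in voom and 48.1%, 56.2% and 45.8% in edgeR. In the KO with age it was 57.0%, but 45.7% in voom, 40.7% in DESeq2 and 28.3%, 32.2% and 28.0% in edgeR. For the difference it was 66.7%, but 33.3% in edgeR. Gene lists called by camera numbered 6 at P17, but 10 without a filter, 11 with a surrogate variable, 0 with an estimated correlation (2 at an unadjusted p under 0.05) and 2 by fry, and 6 to 11 without 1 library (11 without P17 KO 1). They numbered 12 at P31, but 2 with an estimated correlation and 5 by fry, and 10 to 14 without 1 library. With age they numbered 14 in controls, but 9 with the rod covariate, 2 with an estimated correlation and 9 by fry, and 11 to 15 without 1 library, and 7 in the KO, but 1 and 3, and 6 to 10 without 1 library. For the difference they numbered 7, but 1 with the rod covariate, 1 with an estimated correlation and 2 by fry, and 3 to 11 without 1 library (P31 KO 5, P17 KO 1). With an estimated correlation the adjusted p was 0.138 for interferon at P17, 0.0504 for disease-associated microglia and 0.239 for antigen presentation at P31, and 0.318 for lipid efflux and 0.11 for rods with age in controls. The rod list reversed to 0.986 with the rod covariate, which removes it by construction. Without 1 library the adjusted p of camera ranged from 1.07e-18 to 1.6e-05 for interferon at P17, and at P31 from 2.29e-36 to 6e-29 for the cell cycle, 6.93e-15 to 7.36e-11 for interferon, 0.00123 to 0.00714 for disease-associated microglia and 0.000324 to 0.0118 for antigen presentation. With age in controls it ranged from 4.84e-16 to 3.49e-11 for interferon, 1.31e-14 to 3.42e-10 for glycolysis, 0.00238 to 0.013 for lipid efflux and 4.04e-33 to 9.25e-15 for rods, and for the cell cycle from 2.57e-20 to 1.22e-15 with age in the KO and 7.53e-24 to 1.59e-17 for the difference. Deviations of same-numbered libraries correlated between -0.137 and 0.117 and exceeded 0.1 in 2 of 20 pairs. The S numbers thus went with no strong shared variation, which does not exclude that they pair the libraries. Depth limits genes under 3 reads in a library, worth 1.73 to 3.88 normalised counts.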

Other observations

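No explanation was tested in this part, and its genes were chosen after their values were seen. Apoe and Apoc1, which encode lipid carriers, were higher in the KO at both ages, the 2 called of 12 tested lipid efflux genes. That list had medians of -0.14 at P17 (0.34 without P17 KO library 1, camera adjusted p = 0.000101, and adjusted p = 0.129 with an estimated correlation) and 0.28 at P31 (camera adjusted p = 0.0753 and 0.0145, and adjusted p = 0.791 and 0.431 with an estimated correlation). Apoe was higher by 1.38 on the log2 scale at P17 and 1.62 at P31 (limma adjusted p = 0.0239 and 0.00748), and Apoc1 by 2.664 and 4.845 (limma adjusted p = 0.0102 and 1.63e-05). Sparc, an extracellular matrix protein gene on the homeostatic list, was higher by 0.711 and 0.705 (limma adjusted p = 0.00217 and 0.00352), while Slc2a5, on the same list, fell by 5.09 and 6.13. Ldhb, which encodes a lactate dehydrogenase subunit, was higher by 0.81 at both ages (limma adjusted p = 0.00782 and 0.00973). Dgat2, a triglyceride synthesis enzyme, was higher by 4.53 at P31 (limma adjusted p = 0.00077), and Plaur, the urokinase receptor, by 1.06 (limma adjusted p = 0.0286).

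By exact permutation over 252 splits of the P31 libraries, the smallest p possible was 0.00794. It was reached by 7 lists, for which the adjusted p was 0.0374. The score was higher in the KO by 2.90 for the cell cycle, 0.75 for disease-associated microglia, 0.59 for lipid uptake and 0.28 for oxidative phosphorylation, and fell by 1.42 for interferon, 0.38 for homeostatic microglia and 0.30 for antigen presentation. With an estimated correlation the camera adjusted p was 0.397 for lipid uptake, 0.483 for oxidative phosphorylation and 0.721 for homeostatic microglia, the last at 0.123 with the preset correlation. At P17, interferon was the list with an adjusted p under the threshold, at 0.0416. Ribosomal protein genes had medians of 0.41 at P17 and 0.43 at P31, with 0 of 61 called over all genes at either age by limma and camera adjusted p = 0.783 and 0.503 with an estimated correlation. Without P17 KO library 1 the P17 median of this list was 0.03 (camera adjusted p = 0.771).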
